A study of Mus musculus with 51 samples.

How the data were processed

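RNA was measured in Ly6G+ neutrophils of 4 mouse tissues (15 libraries) and in ER-Hoxb8 neutrophils (28 libraries), and open chromatin in 8 ATAC-seq libraries of the same tissues. The 4 deposited tables hold counts per the file headers, that is, raw read pairs per gene made with featureCounts. The tissue table was counted without regard to strand and the ER-Hoxb8 tables as reverse stranded. According to the submitters' processing notes, which give tool names only, RNA reads were aligned with STAR and tested with DESeq2, and ATAC-seq reads were trimmed with cutadapt, aligned with Bowtie2 to mm10, called with MACS2 and compared with DESeq2. The lists of differential sites that the authors deposited hold neg_log10_p values (-log10 of the adjusted p), whose lowest value lay just above the one for 0.05 in every list. The merged sites that the authors deposited hold a score of unknown scale, and 2 columns of another unit (other), the number of merged peaks and the width in bp.

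Groups were taken from the labels. The tissue columns carry a tag and a number from m1 to m4, which match no number in the sample titles and whose meaning is not stated, so a replicate there is only a column. In set 1, 18 columns that match no sample of the series were left out, 10 of them sums of a pair of others. RUNX1-/- and KLF6-/- cells come from a later table of set 2, whose 6 columns checked against the first table were identical. Of 50600 gene IDs, 50376 were matched to symbols (99.6%). Libraries were treated as unpaired.

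Counts were fitted with edgeR 4.0.16 (quasi-likelihood, TMM scaling) in R 4.3.3, one fit per table: 12330 genes in the tissues, 12899 in set 1, 13779 in set 2 and 13874 in the later table. Genes were kept by filterByExpr with a count minimum of 10, a total minimum of 15 and a share of 0.7. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and a 2-fold call needs an absolute log2 change of 1 as well. Interaction terms compared the zymosan response of each line with that of its wild type. The common biological coefficient of variation was 1.86 in the tissues and 0.028, 0.019 and 0.018 in the ER-Hoxb8 fits. Totals ranged from 9.24 to 19.1 M read pairs in the tissues, 19.4 to 32.4 in set 1, 24.0 to 34.3 in set 2 and 26.9 to 30.2 in the later table. Lower bounds of fold changes against groups with 0 counts use a floor of 3 counts over the group. The reads carry no molecular identifiers, so floors cover counting error only.

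The method was tested on simulated data, with 100 changed genes at each size. At the spread of the tissue libraries edgeR found 1% of 4-fold and 32% of 64-fold changes with 3 false calls, and DESeq2 found 6% and 66% with 249 false calls. At the spread of the ER-Hoxb8 libraries edgeR found 100% of 2-fold changes, with 8 to 13 false calls.

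Before the data were examined, 29 gene lists with 428 genes were fixed: azurophil, specific and gelatinase granule, cytokine, chemokine, NF-kB pathway, immediate early, interferon stimulated, NADPH oxidase, glycolysis, hypoxia response, oxidative phosphorylation, ribosomal protein, adhesion and migration, pattern recognition, cell survival and death, heat shock, cell cycle, neutrophil transcription factors, and markers of progenitors, monocytes, dendritic cells, B cells, T and NK cells, eosinophils and mast cells, erythroid cells, platelets, fibroblasts, and endothelium with keratinocytes. They were tested with camera in limma 3.58.1 at a preset correlation of 0.01, again with an estimated correlation, and with fry. Over the ER-Hoxb8 comparisons 4777 list members were called over all genes and 4814 adjusted over the list alone, a gap of at most 3 in any list. List scores are means of log2(CPM + 1). The 6 factors and the list scores were compared between tissues by two-sided exact permutation tests. The naming rule, set at the same time as the groups, comparisons and alternatives, took the targeted gene, the called genes with the largest changes at a mean log2 CPM of 4 or more in non-overlapping libraries, up to 4 called members per list, the 6 factors, and the 10 most abundant genes.

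Site lists were intersected with the merged sites with bedtools 2.31.1 and GenomicRanges 1.54.1, and overlaps were tested with Fisher's exact test. Sites were assigned to gene starts within 50000 bp, and positions at gene starts were counted within 1000 bp. Median expression changes near sites were compared by 10000 permutations. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.

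Alternatives were RLE scaling, DESeq2 1.42.0, no filter on low counts, fits of only the compared groups, a replicate block, each library left out in turn, a 2-fold threshold, and other distances and overlaps for sites. Added after the data were seen were total-count scaling, voom with and without library weights, a term for the tags 100 and 300 in the tissue column names, fits of 1 tag alone, and blocks by the tag and number of the tissue columns. Motifs were not searched, since no genome sequence was at hand.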

Results

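Neutrophils that had entered a zymosan-inflamed air pouch were compared with neutrophils of blood and bone marrow, and 6 transcription factors were examined in a cultured neutrophil line. In mice, 100 µg zymosan, a yeast cell wall particle, was injected into a 6-day dorsal air pouch, and Ly6G+ cells were collected 4 h later from bone marrow, blood, the pouch membrane and the pouch exudate. Open chromatin was profiled by ATAC-seq in 2 libraries per tissue, from 75000 cells each. RNA was profiled with a small-bulk Smart-seq2 method in 5 exudate, 5 blood, 3 bone marrow and 2 membrane libraries. ER-Hoxb8 neutrophils are conditionally immortalised progenitors that mature when the Hoxb8 transgene is switched off. They were differentiated for 5 days and then given DMSO or zymosan at 50 µg/ml for 2 h, with 2 RNA libraries per group. Set 1 held wild-type, CEBPB-/- and JUNB-/- cells, and set 2 held wild-type, IRF5-/- and RELB-/- cells. RUNX1-/- and KLF6-/- cells were sequenced with DMSO only and were compared with the wild type of set 2.

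The tissue RNA libraries held between 9.24 and 19.1 M counted read pairs. By group, the totals were 15.5 ± 2.96 M (SD, n = 5) in exudate, 13.1 ± 2.02 (n = 5) in blood, 13.9 ± 4.70 (n = 3) in bone marrow and 13.8 ± 1.95 (n = 2) in membrane. Neutrophil transcripts dominated them: over all 15 libraries the highest mean levels were those of S100a8 (153400 CPM) and S100a9 (45120 CPM), which encode calprotectin, followed by the ferritin gene Fth1 (32050 CPM). Replicates of a tissue correlated weakly across genes, at Spearman rho 0.356 to 0.714. The ER-Hoxb8 libraries held 19.4 to 34.3 M read pairs, and their replicates correlated at rho 0.992 to 0.998. Standard errors and p-values there measure the spread between these replicates, not between separately made lines or cultures of a genotype. In a joint fit, the wild types of both sets differed at 9766 of 14405 genes with DMSO. Levels are given as CPM, counts scaled by library size and the TMM factors of the fit (mean ± SD), and changes as log2 fold changes with their standard error. The wild type of set 2 therefore has other CPM values beside RUNX1-/- and KLF6-/- cells than beside IRF5-/- and RELB-/- cells.

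The first comparison asked how neutrophils changed on leaving the bone marrow. Specific granule genes, made late in the marrow (such as Ltf, lactoferrin), had a mean score of 8.05 ± 1.71 log2 CPM (n = 5) in blood and 10.75 ± 0.24 (n = 3) in bone marrow. Their list was lower in blood (adjusted p = 1.27e-08 by camera; adjusted p = 0.103 with an estimated correlation). Irgm1, an interferon-induced GTPase, stood at 363 ± 419 CPM in blood (n = 5) and at 0 counts in the 3 bone marrow libraries, at least 6300-fold higher in blood. This bound and those below cover counting error only, not the spread between libraries. Mefv, which encodes the inflammasome protein pyrin, stood at 122 ± 126 CPM against 0, at least 2110-fold higher. These 2 genes were the whole list of called genes (edgeR, adjusted p = 0.0491 and adjusted p = 0.0244), and they are named after their values were seen. The interferon stimulated list scored 5.18 ± 2.85 in blood and 2.82 ± 0.12 in bone marrow (adjusted p = 0.0136; adjusted p = 0.669 with an estimated correlation), with 8 of 22 members called when adjusted over the list alone and 0 over all genes. The blood mean rested on libraries 1 and 2, with scores of 7.85 and 8.65, since the other 3 lay between 2.46 and 3.57. Across all genes these 2 libraries had their highest mean rho with membrane (0.534 and 0.56, against 0.531 and 0.54 with blood), and blood libraries 3 to 5 with bone marrow (0.574 to 0.655, against 0.533 to 0.559 with blood). Pattern recognition (adjusted p = 0.0119; adjusted p = 0.489 with an estimated correlation) and cytokine genes (adjusted p = 0.0264; adjusted p = 0.563 with an estimated correlation) were higher, and oxidative phosphorylation genes lower (adjusted p = 0.00137; adjusted p = 0.103 with an estimated correlation). At an unadjusted p under 0.05 there were 1438 genes. DESeq2 called 237 genes and voom 43. A block by column tag and number, described below, raised the edgeR count. In edgeR the count was 0 without any one of the bone marrow libraries 1, 2 or 3, 1 without blood library 1, 2 or 3, and 0 with only blood libraries 3 to 5.

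The step from blood into the pouch was addressed by membrane against blood and exudate against blood. Interferon stimulated genes scored 9.33 ± 0.66 log2 CPM in membrane (n = 2), 7.61 ± 3.02 in exudate (n = 5) and 5.18 ± 2.85 in blood (n = 5), where libraries 1 and 2 again stood apart from the other 3. The list was higher in membrane (adjusted p = 2.42e-17; adjusted p = 0.133 with an estimated correlation) and in exudate (adjusted p = 1.91e-08; adjusted p = 0.382 with an estimated correlation). Chemokine genes scored 9.25 ± 0.07 in membrane, 8.30 ± 3.38 in exudate and 5.65 ± 3.25 in blood (adjusted p = 0.000285 and 0.00155; adjusted p = 0.266 and 0.382 with an estimated correlation). Specific granule genes scored 4.90 ± 1.52 in membrane and 5.62 ± 1.27 in exudate, against 8.05 ± 1.71 in blood (adjusted p = 0.0195 and 0.0343; adjusted p = 0.375 and 0.428 with an estimated correlation). In membrane, hypoxia response genes scored 5.35 ± 0.70 against 3.54 ± 1.15 in blood, and this list kept its call with an estimated correlation (adjusted p = 3.77e-06 preset, adjusted p = 0.0396 estimated). The adhesion and migration list kept its call in membrane too (adjusted p = 0.00061 preset, adjusted p = 0.0396 estimated), with a median log2 change of 0.39 that became -0.11 with total-count scaling. The scores of these 2 lists had exact permutation p = 0.19 and 0.143 (adjusted 0.392 each). For pattern recognition genes in membrane the median (1.32) and the test were positive and the mean (-0.07) was negative (adjusted p = 0.124 with an estimated correlation). In exudate, NF-kB pathway (adjusted p = 6.82e-07; adjusted p = 0.382 with an estimated correlation), immediate early (adjusted p = 1.91e-08; adjusted p = 0.205 with an estimated correlation) and cytokine genes (adjusted p = 0.000925; adjusted p = 0.413 with an estimated correlation) were higher than in blood. Between exudate and membrane, hypoxia response genes were lower in exudate (3.35 ± 0.71, n = 5), with adjusted p = 1.5e-05 and adjusted p = 0.0803 with an estimated correlation.

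No single gene passed the edgeR test between membrane and blood, between exudate and membrane or between exudate and blood, where 963, 1014 and 2349 genes had an unadjusted p under 0.05. DESeq2 called 1087, 792 and 1003 genes in these comparisons, and voom called 172, 52 and 174. With a block by column tag and number, described below, edgeR called genes in each of them. Of the list members, 3, 2 and 7 were called when adjusted over the list alone. With only blood libraries 3 to 5, edgeR called 7 genes between membrane and blood and 31 between exudate and blood. Leaving out exudate library 5 gave 14 genes between exudate and blood, and 264 with only blood libraries 3 to 5. That library stood apart from the other exudate libraries, with an interferon stimulated score of 2.21.

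**Figure D1:**
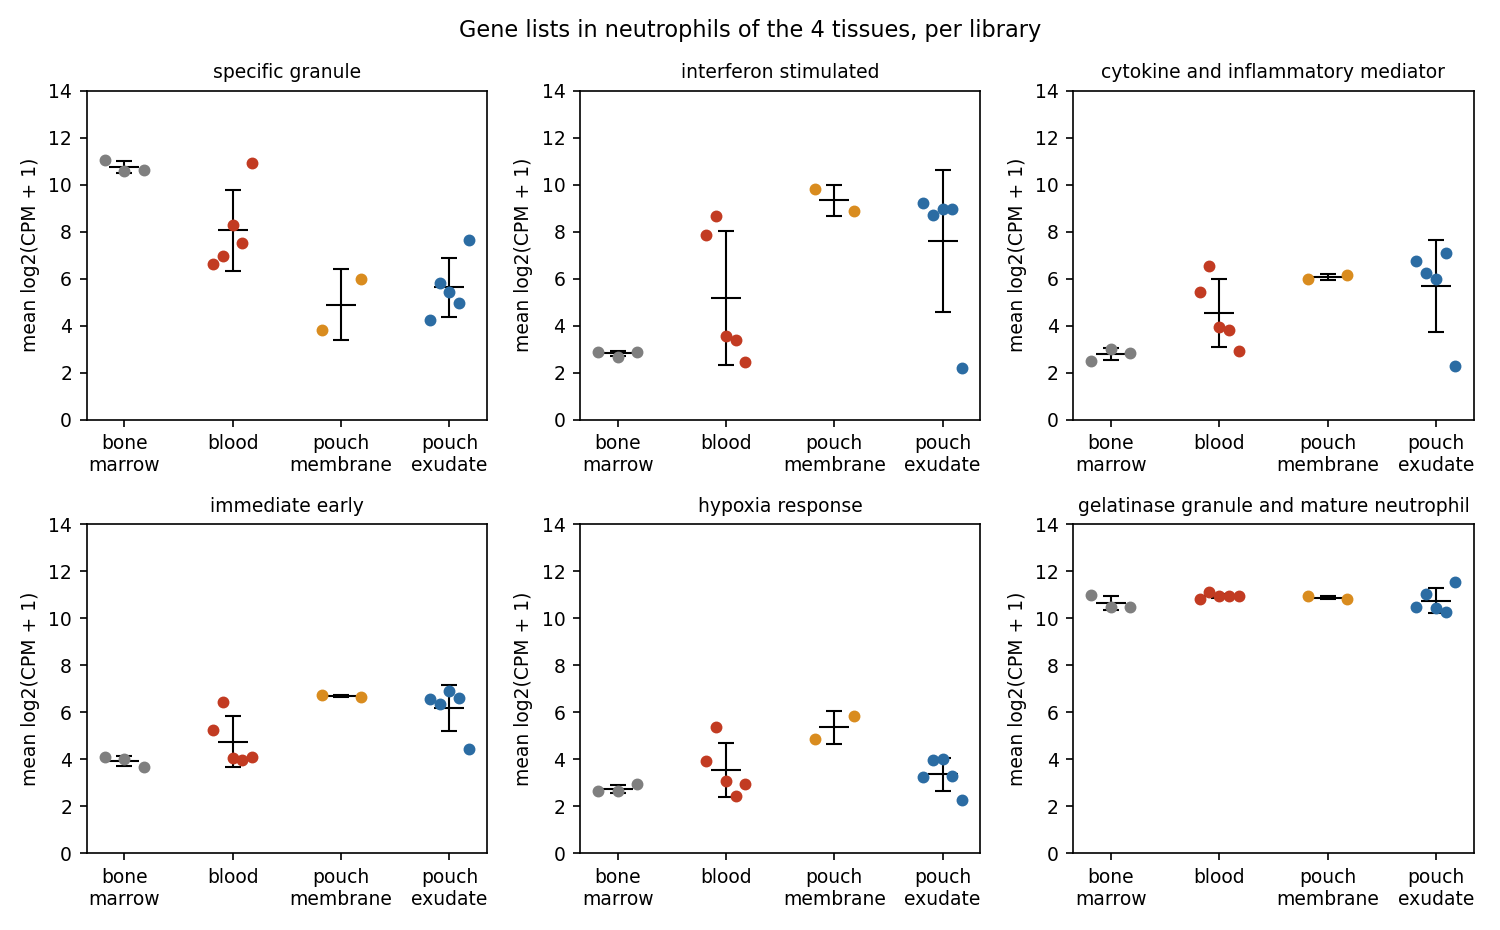
Mean log2(CPM + 1) of 6 gene lists (y axis) in neutrophils of the 4 tissues (x axis); each point is a library, the bar is the mean and the whiskers are the SD. Specific granule genes averaged 10.75 in bone marrow and 5.62 in exudate, while gelatinase granule genes stayed between 10.63 and 10.95 in every tissue.

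Between exudate and bone marrow, edgeR called 22 genes, 8 higher and 14 lower in exudate. Il1b, the interleukin-1 beta gene, rose to 11390 ± 5804 CPM (n = 5) from 48.0 ± 48.2 (n = 3), a log2 change of 7.89 (SE 1.64, adjusted p = 0.0493). Fth1, the ferritin heavy chain, rose by 3.63 (SE 0.68, adjusted p = 0.0395). Clec4d, a C-type lectin receptor for fungal and mycobacterial glycans, rose by 4.17 (SE 0.85). Hdc, the histamine-forming enzyme, rose by 3.08 and Mxd1, a MYC antagonist of mature cells, by 2.92. Chil3, a chitinase-like protein of marrow neutrophils, fell from 3503 ± 606 CPM to 3.34 ± 5.60 (log2 change -10.03, SE 1.94, adjusted p = 0.0493). Outside the naming rule, and chosen after their values were seen, Irgm1 (at least 14700-fold), Mefv (at least 5280-fold) and Il15ra, the interleukin-15 receptor alpha gene (at least 3980-fold), were called higher with 0 counts in bone marrow. Aprt, an adenine salvage enzyme, was at least 2340-fold lower, with 117 ± 45.0 CPM in bone marrow and 0 counts in exudate.

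Against bone marrow, camera called 11 lists in exudate and 16 in membrane, and 0 of either kept the call with an estimated correlation. Interferon stimulated genes scored 2.82 ± 0.12 in bone marrow (n = 3), and 18 of 22 members were called in exudate when adjusted over the list alone against 0 over all genes. The list was higher in exudate (adjusted p = 3.31e-07; adjusted p = 0.267 with an estimated correlation) and in membrane (adjusted p = 2.87e-13; adjusted p = 0.138 with an estimated correlation). Chemokine genes scored 3.03 ± 0.67 in bone marrow, and 8 of 9 were called in exudate over the list alone (adjusted p = 0.00162; adjusted p = 0.267 with an estimated correlation). Cytokine genes scored 2.78 ± 0.26 in bone marrow and 5.67 ± 1.95 in exudate, and 8 of 18 were called over the list alone (adjusted p = 0.000148; adjusted p = 0.267 with an estimated correlation; exact permutation p of the score 0.125). Specific granule genes were lower in exudate (adjusted p = 6.69e-06; adjusted p = 0.171 with an estimated correlation) and in membrane (adjusted p = 5.51e-05; adjusted p = 0.112 with an estimated correlation). Hypoxia response genes scored 2.74 ± 0.17 in bone marrow and 3.35 ± 0.71 in exudate, where they were not called, and 5.35 ± 0.70 in membrane (adjusted p = 3.21e-06; adjusted p = 0.0688 with an estimated correlation). Gelatinase granule genes scored 10.63 ± 0.29 in bone marrow, 10.95 ± 0.10 in blood, 10.87 ± 0.07 in membrane and 10.74 ± 0.53 in exudate. Between membrane and bone marrow, edgeR called Irgm1 (1246 ± 487 CPM, n = 2, at least 21600-fold) and Mefv (358 ± 271 CPM, at least 6210-fold) and no other gene, with 1637 genes at an unadjusted p under 0.05 and 1421 called by DESeq2. All bone marrow libraries carry the column tag 100 and both membrane libraries the tag 300. Differences between membrane and bone marrow therefore coincide with the tag, whose meaning is not stated.

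The counts against bone marrow rested on single libraries. For exudate the 22 calls became 0 without bone marrow library 1, 2 or 3, 1 without exudate library 1, 2 without exudate library 2, 3 or 4, and 197 without exudate library 5; with only the compared groups in the fit there were 0. For membrane the 2 calls became 0 without bone marrow library 1, 2 or 3, and with only the compared groups there were 128. DESeq2 called 1414 genes and voom 968 for exudate. A block by column tag and number, described below, raised the edgeR counts for exudate and for membrane. On simulated libraries of this spread edgeR found 1% of 4-fold and 32% of 64-fold changes with 3 false calls, and DESeq2 found 6% and 66% with 249 false calls.

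Lists of other cell types were measured too, and several were highest in bone marrow. The T and NK cell list scored 2.28 in blood, 2.5 in bone marrow, 0.36 in exudate and 0 in membrane, and the B cell list 1.69, 2.81, 0.71 and 0.64. The erythroid list scored 3.41 ± 3.72 in bone marrow (n = 3) and at most 0.43 elsewhere, and was lower in blood (adjusted p = 0.00081; adjusted p = 0.103 with an estimated correlation). Monocyte and macrophage genes scored 2.09 ± 0.02 in bone marrow and 3.65 ± 0.98 in blood (n = 5), and were called higher in blood (adjusted p = 0.0136; adjusted p = 0.357 with an estimated correlation). Dendritic cell and MHC class II genes scored 2.08 in exudate and 0.94 in blood (adjusted p = 0.0257; adjusted p = 0.382 with an estimated correlation). The eosinophil and mast cell list scored 1.58 in exudate, platelet genes 0.86 and fibroblast genes 0.24. Eosinophil and mast cell (difference 1.4) and monocyte genes (1.25) were higher in all exudate than in all bone marrow libraries (exact permutation p = 0.0893 and 0.143). The progenitor list scored between 0.95 and 2.07 in the 4 tissues, and cell cycle genes between 0.44 and 1.6. Of these, the T and NK cell, eosinophil and mast cell, and platelet lists held 2 measured genes each. The erythroid and progenitor lists held 3, the fibroblast list 4 and the monocyte list 5.

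The 6 factors studied in culture were also compared across tissues. Junb, an AP-1 subunit, stood at 396 ± 74.6 CPM in exudate (n = 5) and 169 ± 78.7 in blood (n = 5), with exact permutation p = 0.00794 over 252 splits and 0.0476 after adjustment over the 6 genes. The adjusted p was 0.238 with total-count scaling, and between 0.0667 and 0.0952 without any one exudate library. Klf6, a Krüppel-like factor, stood at 904 ± 508 CPM in exudate and 322 ± 208 in blood (exact permutation p = 0.0317, adjusted 0.0634). Cebpb, a granulocytic C/EBP factor, stood at 166 ± 45.9 and 86.1 ± 43.5 CPM (exact permutation p = 0.0317, adjusted 0.0634), and at 30.6 ± 4.49 in bone marrow (n = 3). Runx1 (48.8 ± 36.5 and 14.7 ± 11.3 CPM) and Irf5 (52.4 ± 44.6 and 13.1 ± 13.4) had adjusted exact p = 0.4. Relb, an NF-kB subunit, stood at 73.7 ± 97.1 and 26.2 ± 15.7 CPM (adjusted exact p = 0.865).

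ATAC-seq addressed which regulatory sites opened or closed along the same path, as lists of differential sites that the authors deposited. In exudate 2834 sites were more and 1086 less accessible than in blood, and in membrane 2228 were more and 905 less accessible. Between blood and bone marrow the lists held 559 and 383 sites. The site with the lowest adjusted p in exudate against blood lay on chromosome 1 at 173766439 to 173767672 (mm10), over an exon of the interferon-inducible gene Ifi204 (-log10 adjusted p 51.3). A site over a Klf6 intron on chromosome 13, at 5866078 to 5866582, a site over an exon at the start of Irf5 on chromosome 6, at 29526394 to 29527344, and a site on chromosome 8 by Junb, at 84976071 to 84976930, were more accessible in exudate than in blood (-log10 adjusted p 4.17, 9.46 and 10.2). Runx1 had a listed site at 92823548 to 92824084 on chromosome 16 (5.27). Near Cebpb, a site at 167686437 to 167686961 on chromosome 2 was more accessible in exudate than in bone marrow (8.32), and no site near Relb was listed. The deposited lists give no accessibility per library, so their spread between replicates is not known.

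**Figure D2:**
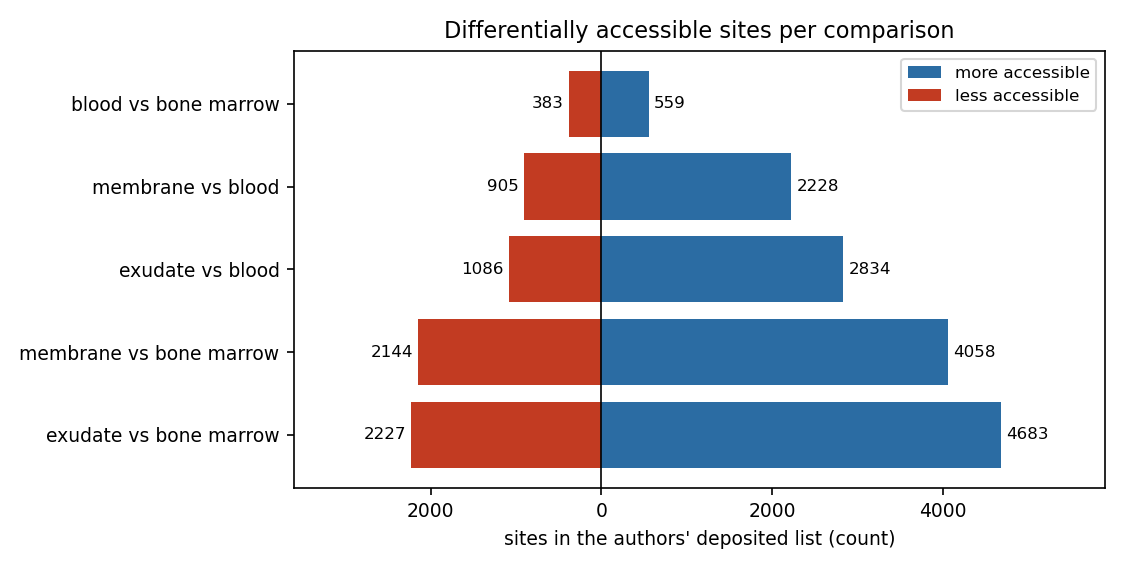
Number of sites in each deposited list (x axis) for 5 tissue comparisons (y axis), more accessible to the right and less accessible to the left of 0. Against bone marrow 4683 sites were more accessible in exudate and 4058 in membrane, but 559 in blood.

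Membrane and exudate shared many of the sites that opened. Of the 2834 sites more accessible in exudate than in blood, 1914 (67.5%) were also more accessible in membrane than in blood, lists that share the blood libraries. In lists that share no library, 2109 of them (74.4%) were more accessible in membrane than in bone marrow, against 244 expected by chance over the 47164 merged sites. Of the 1086 sites less accessible in exudate than in blood, 458 (42.2%) were less accessible in membrane than in bone marrow, against 49.4 expected. Sites that changed lay away from gene starts: 450 of the 2834 sites more accessible in exudate than in blood (15.9%) lay within 1000 bp of a gene start, against 31.4% of the 37712 sites in no list (Fisher's exact odds ratio 0.413). Across 9 of the 10 lists the odds ratio was between 0.229 and 0.645. The list of sites less accessible in blood than in bone marrow had 0.881 (exact p = 0.293).

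Sites more accessible in exudate than in blood lay near genes of the inflammatory lists. Of 1752 genes with a site more accessible in exudate than in blood within 50000 bp, out of 19575 genes, 18 belonged to the 21 interferon stimulated genes (adjusted Fisher's exact p = 3.46e-14). NF-kB pathway genes held 14 of 20 (adjusted exact p = 4.19e-09), cytokine genes 13 of 20 (3.72e-08) and chemokine genes 7 of 10 (5.5e-05). The expression scores of these 4 lists in exudate against blood had exact permutation p = 0.23, 0.151, 0.341 and 0.27, and their calls were lost with an estimated correlation (adjusted p = 0.382, 0.382, 0.413 and 0.382). Of the neutrophil transcription factors, 7 of 16 had such a site, namely Gfi1, Irf5, Junb, Klf6, Nfil3, Runx1 and Spi1. Glycolysis genes held 5 of 16 among those near less accessible sites (Eno1, Gpi1, Ldha, Pgam1 and Slc16a3, adjusted exact p = 0.00227), as did 4 gelatinase granule genes, S100a8, S100a9, Lrg1 and Retnlg (adjusted exact p = 0.0113). In blood against bone marrow, 5 of 9 specific granule genes (Abca13, Camp, Cd177, Ltf and Ngp) lay near sites that had become less accessible (adjusted exact p = 1.55e-06).

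Near opened sites, expression changed upward relative to genes near sites in no list. Genes near sites more accessible in exudate than in blood had a median log2 expression change of 0.83, against -0.60 for genes near sites in no list (permutation p = 1e-04, the smallest that 10000 permutations can give). The medians were 0.63 against -2 in membrane against blood, 1.78 against -0.25 in exudate against bone marrow and 1.31 against -1.41 in membrane against bone marrow. In DESeq2 the differences were 0.94, 1.53, 0.75 and 0, the last of which (membrane against bone marrow) was not called, and without a filter 1.07, 1.58, 1.33 and 0.13. Near less accessible sites the direction varied. Membrane against bone marrow had -2.17 against -1.41 (permutation p = 0.001), in the direction of the chromatin, a difference of -0.76 that was 0 and not called without a filter. Exudate against bone marrow had -0.52 against -0.25 (permutation p = 0.05), and this difference of -0.27 was -0.63 within 10000 bp (permutation p = 3e-04) and -0.09 within 100000 bp (permutation p = 0.5). Membrane against blood had -1.95 against -2 (permutation p = 0.9) and blood against bone marrow -0.17 against 0.16 (permutation p = 0.08). Exudate against blood had -0.03 against -0.60 (permutation p = 0.001), a difference of 0.57 against the direction of the chromatin that became -0.07 in the 300-tagged libraries alone and was not called in DESeq2 (0.27), in voom (0.03) or with only blood libraries 3 to 5 (0.32). The median of all genes was -1.74 in membrane against blood, and genes are not independent replicates.

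Zymosan in culture tested whether the particle alone gave part of this response. In wild-type ER-Hoxb8 cells it raised cytokine and chemokine genes. Il23a, the p19 subunit of interleukin-23, rose from 1.21 ± 0.145 to 482 ± 26.1 CPM (n = 2) in set 1, a log2 change of 8.64 (SE 0.07, adjusted p = 1.57e-64), and by 6.88 in set 2. Il1a, the interleukin-1 alpha gene (chromosome 2, 129299610 to 129309972), rose from 21.3 ± 0.454 to 3408 ± 107 CPM in set 1 (7.32, SE 0.04) and from 20.6 ± 0.0123 to 3139 ± 26.3 in set 2 (7.25, SE 0.03). Nfkbiz, an inducible NF-kB cofactor, rose by 5.29 and 4.24, the chemokine gene Ccl4 by 5.30 and 5.62, and Clec4e, the Mincle receptor gene, by 3.13 and 2.79. Cxcr2, the receptor for neutrophil-attracting chemokines, fell from 1590 ± 1.86 to 115 ± 0.612 CPM in set 1 (log2 change -3.79, SE 0.04) and from 1121 ± 9.12 to 190 ± 4.83 in set 2 (-2.56). Selplg, the selectin ligand gene, fell by 1.61 and 1.49 on the log2 scale, and Cebpd by 2.34 and 2.65. Of the most changed genes, Nr4a3, Areg and Lif rose in set 1 by 6.92, 6.64 and 6.56, Serpinb2 and Cxcl3 rose in set 2 by 7.09 and 6.61, and Gpr146 and Sema6b fell in set 1 (-5.13 and -4.10).

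As groups, all 21 measured cytokine genes rose in both sets (median log2 change 3.85 and 3.69). NF-kB pathway genes rose, 20 of 21 in set 1 and 21 of 21 in set 2 (3.08 and 2.46), and both lists kept their calls with an estimated correlation (adjusted p = 0.0053 and 0.0291 in set 1, 0.00622 and 0.0125 in set 2). Hypoxia response genes rose, 12 of 14 in set 1 (0.85, adjusted p = 0.0291 with an estimated correlation). Chemokine genes rose in set 1, 12 of 13 (4.48, adjusted p = 0.0291 with an estimated correlation), and 11 of 12 in set 2 (2.82, adjusted p = 0.0779 with an estimated correlation). Immediate early genes rose by a median of 2.03 in set 1 and 1.85 in set 2, with adjusted p = 0.155 and adjusted p = 0.0125 with an estimated correlation. Glycolysis genes rose by 0.86 in set 1 (adjusted p = 0.124 with an estimated correlation) and 1.72 in set 2 (adjusted p = 0.0141 with an estimated correlation), with Ldha up by 1.6 and 2.63. Pattern recognition genes rose by 0.86 and 1.40 (adjusted p = 0.225 and adjusted p = 0.0476 with an estimated correlation). Heat shock genes rose by 1.01 and 0.82, the latter becoming -0.06 with total-count scaling. In set 2 specific granule genes rose by 0.67, NADPH oxidase genes by 0.55 and transcription factors by 0.82 (adjusted p = 0.0253, adjusted p = 0.0779 and adjusted p = 0.0956 with an estimated correlation), and total-count scaling turned these to -0.20, -0.32 and -0.06. Ribosomal protein (0.53) and cell cycle genes (0.43) rose in set 1, became -0.18 and -0.27 with total-count scaling, and had adjusted p = 0.124 each with an estimated correlation. Transcription factors (0.81) and platelet genes (1.29) rose in set 1 too, with adjusted p = 0.342 and adjusted p = 0.234 with an estimated correlation.

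The remaining lists were not called in set 1. These were the specific granule (median 0.25, adjusted p = 0.186), azurophil granule (median -0.47, adjusted p = 0.59), gelatinase granule (-0.31, adjusted p = 0.0999) and interferon stimulated genes (-0.21, adjusted p = 0.47), with NADPH oxidase (adjusted p = 0.355), dendritic cell and MHC class II (adjusted p = 0.153), oxidative phosphorylation (adjusted p = 0.421), adhesion and migration (adjusted p = 0.153), cell survival and death (adjusted p = 0.355), progenitor (adjusted p = 0.153), monocyte (adjusted p = 0.776), B cell (adjusted p = 0.636), T and NK cell (adjusted p = 0.664), eosinophil (adjusted p = 0.288) and fibroblast genes (adjusted p = 0.0956). The endothelial and keratinocyte list, with 2 members measured in set 2, had adjusted p = 0.465 there.

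In set 1, 4608 genes rose and 5143 fell, 4720 of them at least 2-fold. In set 2, 4997 rose and 4421 fell, 4010 at least 2-fold. Across 12395 genes the responses of both wild types correlated at Pearson r = 0.843; 1577 genes rose at least 2-fold in both (370 expected), 1251 fell in both, and 10 went opposite ways. Total-count scaling moved the median of all genes by -0.70 in set 1 and -0.87 in set 2, and the share of called genes that rose went from 47.3% to 22.6% and from 53.1% to 16.4%. Of 280 list calls in the study, 22 changed the sign of their median with total-count scaling and 0 with RLE scaling.

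The response in the pouch was set beside the response in culture. Across 9401 genes the exudate against blood changes and the wild-type zymosan changes of set 1 correlated at r = 0.189, and across 9774 genes those of set 2 at r = 0.210, with genes not independent replicates. Genes that zymosan raised in culture had a median log2 change of 0.67 and 0.78 in exudate, and genes that it lowered -1.22 and -1.41. Leaving out exudate library 5 gave r = 0.242 and 0.264. The zymosan-raised genes were also near the sites that opened. In set 1 they made up 438 of 1079 expressed genes near a site more accessible in exudate than in blood (40.6%), against 1129 of 7508 genes near no listed site (15%; Fisher's exact odds ratio 3.86, adjusted p = 3.56e-76). In set 2 they made up 423 of 1095 (38.6%) against 949 of 7806 (12.2%; odds ratio 4.55, adjusted exact p = 7.45e-91). Zymosan-lowered genes of set 1 made up 9.64% against 18.6% (odds ratio 0.468). Zymosan-raised genes were not confined to opened sites. Near sites less accessible in exudate than in blood their odds ratio was 1.29 in set 1 (adjusted exact p = 0.0845) and 1.61 in set 2 (adjusted exact p = 5.18e-04). Near sites less accessible in blood than in bone marrow it was 2.34 and 2.37 (adjusted exact p = 3.6e-06 and 7.64e-06).

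The transcript of the targeted gene was not lost in the lines labelled knockout. Cebpb (chromosome 2, 167688915 to 167690418) stood at 524 ± 18.9 CPM (n = 2) in CEBPB-/- and 507 ± 40.7 in wild-type cells with DMSO (log2 change 0.05, SE 0.06, adjusted p = 0.503; -0.31 with total-count scaling), and at 2535 ± 488 against 1004 ± 93.5 with zymosan (1.34). Junb fell from 900 ± 69.0 to 499 ± 18 CPM (-0.85) in JUNB-/- cells with DMSO and from 2305 ± 107 to 2121 ± 52.2 (-0.12) with zymosan. Irf5 fell from 98.6 ± 3.97 to 81.4 ± 0.519 CPM (-0.28) in IRF5-/- cells, and Relb from 170 ± 2.55 to 67.9 ± 0.574 (-1.32) in RELB-/- cells with DMSO. With zymosan Irf5 stood at 109.9 ± 2.278 CPM against 136.5 ± 0.2554 in wild type, and Relb at 373.1 ± 5.695 against 458.3 ± 15.29. Runx1 was higher in RUNX1-/- cells, at 151 ± 1.88 against 59.1 ± 1.5 CPM (1.35), and so was Klf6 in KLF6-/- cells, at 828 ± 3.07 against 616 ± 11 (0.43). Counts per gene cannot show an edit within the transcript, and protein was not measured. Whether any line carries a wrong label was not tested. The wild types of both sets differed too: in a joint fit of 14405 genes they were at least 2-fold apart at 3448 genes with DMSO and 3603 with zymosan, where the 4 lines with zymosan libraries differed from their own wild type at 2202 to 4753 and 2309 to 5152. With DMSO, 2222 of 3348 such genes in CEBPB-/-, 3311 of 4753 in JUNB-/-, 2129 of 2839 in IRF5-/- and 1498 of 2202 in RELB-/- cells were at least 2-fold changed the same way against both wild types, and with zymosan 1962 of 3656, 3119 of 5152, 2258 of 2922 and 1681 of 2309.

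**Figure D3:**
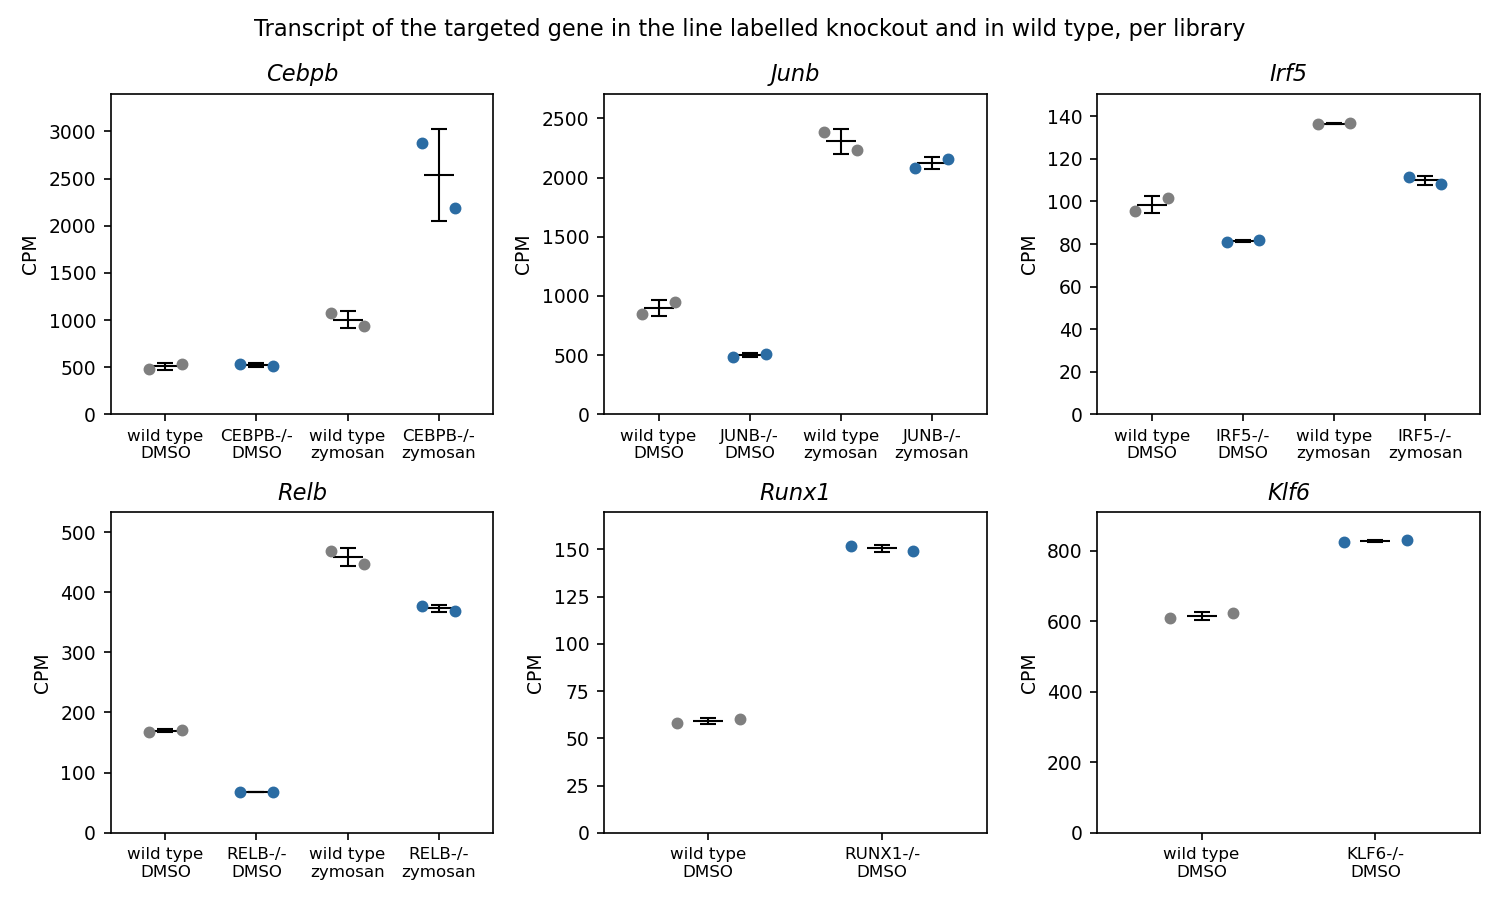
CPM (y axis) of each targeted gene in wild-type cells and in the line labelled knockout (x axis), under DMSO and, where measured, zymosan; points are the 2 libraries, the bar is the mean and the whiskers are the SD. Relb fell from 170 to 67.9 under DMSO, while Runx1 and Klf6 were higher in their own lines.

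Without zymosan, cells labelled CEBPB-/- carried fewer cell cycle and cytokine transcripts than wild type. Btg2, an antiproliferative cofactor gene, fell from 249 ± 6.18 to 1.05 ± 0.181 CPM (n = 2), a log2 change of -7.88 (SE 0.08, adjusted p = 8.61e-60). Cell cycle genes fell in 23 of 24 cases (median -2.49, adjusted p = 0.0195 with an estimated correlation), among them Top2a (-3.56) and the helicase subunit gene Mcm2 (-3.11). Cytokine genes fell in 13 and rose in 2 of 21 cases (-1.31, adjusted p = 0.0476 with an estimated correlation), with Il1a at -3.59, Csf1 at -2.54 and Il1rn at -1.86. Gelatinase granule genes rose in 11 of 14 cases (0.81, adjusted p = 0.0734 with an estimated correlation), with Retnlg, a resistin-like gene of mature neutrophils, up by 2.29. Fgl2, a fibrinogen-like gene, rose by 2.75 and Tmem173, the STING gene, by 2.42. Eosinophil and mast cell genes fell in 7 of 8 cases (-2.01, adjusted p = 0.139 with an estimated correlation), with Ear1 at -5.73 and the peroxidase gene Epx at -3.13. In all, 770 genes were at least 2-fold higher and 2438 at least 2-fold lower.

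With zymosan the same line differed from wild type at 3576 genes by at least 2-fold, 1210 higher and 2366 lower. Fn1, the fibronectin gene, fell from 189 ± 8.13 to 1.38 ± 0.152 CPM (n = 2; log2 change -7.11, SE 0.11, adjusted p = 4.48e-49), Pla2g7, a lipoprotein-associated phospholipase, by 6.74 on the log2 scale, and Slc7a7, an amino acid transporter, rose by 3.84. All 24 cell cycle genes fell (median -2.35, adjusted p = 0.0143 with an estimated correlation). Pattern recognition genes rose in 17 of 18 cases (0.82, adjusted p = 0.0583 with an estimated correlation). The rise with zymosan was larger for inflammatory genes: Il1a rose by 11.31 on the log2 scale against 7.32 in wild type (difference 4.06, SE 0.10, adjusted p = 8.4e-40), reaching 4744 ± 93.0 CPM, and the nuclear receptor gene Nr4a1 by 8.83 against 5.20. For Il1a most of this difference lay in its lower level with DMSO, given above. The response was larger in 19 of 21 NF-kB pathway genes (median difference 1.16, adjusted p = 0.0189 with an estimated correlation) and in 14 of 21 cytokine genes (1.28, adjusted p = 0.0107 with an estimated correlation). Slc7a5, an amino acid transporter gene, fell by 0.84 on the log2 scale where it rose by 1.29 in wild type. The difference in response was called for 5294 genes, 1444 of them at least 2-fold.

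Before any stimulus, cells labelled JUNB-/- carried more granule and fewer inflammatory transcripts than wild type. Ltf, lactoferrin, rose from 356 ± 9.49 to 5203 ± 40.3 CPM (n = 2), a log2 change of 3.87 (SE 0.03, adjusted p = 1.05e-61), and Icam1, an adhesion molecule, fell from 143 ± 2.96 to 3.99 ± 0.0812 (-5.16, SE 0.06, adjusted p = 6.61e-56). Specific granule genes rose in 10 of 11 cases (median 2.24), with Ngp at 3.22 and Cd177 at 3.13, and gelatinase granule genes rose in 14 of 14 (1.14; both lists had adjusted p = 0.0391 with an estimated correlation). NADPH oxidase genes rose in 5 of 6 cases (0.87), with Cybb, the catalytic subunit gene, at 2.12. Interferon stimulated genes fell in 21 of 23 cases (-4.06), chemokine genes in 11 of 13 (-3.12), cell cycle genes in 19 of 24 (-0.93) and eosinophil and mast cell genes in 8 of 8 (-3.56), each with adjusted p = 0.0391 with an estimated correlation. NF-kB pathway genes fell in 19 of 21 (-1.37, adjusted p = 0.053 with an estimated correlation). At least 2-fold, 1415 genes were higher and 3148 lower.

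With zymosan, JUNB-/- cells were at least 2-fold higher at 2034 genes and lower at 2986. The prostaglandin synthase gene Ptgs2 reached 1695 ± 18.6 CPM against 6670 ± 220 in wild type (n = 2; log2 change -1.98), Ccl2, a monocyte chemokine gene, 20.0 ± 0.0868 against 480 ± 26.0 (-4.58), and Lif stayed lower by a log2 change of -2.83. Ltf stayed higher (3873 ± 55.1 against 424 ± 4.11 CPM, 3.19). Interferon stimulated genes were lower in 22 of 23 cases (median -2.92), chemokine genes in 12 of 13 (-2.60) and cytokine genes in 13 of 21 (-1.07), each with adjusted p = 0.0245 with an estimated correlation. Gelatinase granule genes were higher in 14 of 14 cases (1.57, adjusted p = 0.0164 with an estimated correlation). The rise with zymosan was nonetheless larger for part of the inflammatory genes: Icam1 rose by 9.01 on the log2 scale against 3.51 in wild type (difference 5.54, SE 0.07, adjusted p = 6.27e-53), and Egr3 had a difference of 6.51. Their lower levels with DMSO (log2 changes of -5.16 and -5.9) made up most of these differences. The response was larger in 22 of 23 immediate early genes (median 1.51, adjusted p = 0.0821 with an estimated correlation) and 19 of 21 NF-kB pathway genes (1.39, adjusted p = 0.0667 with an estimated correlation), and smaller for the activin gene Inhba (2.97 against 4.77). The difference in response was called for 5619 genes, 1622 of them at least 2-fold.

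In cells labelled IRF5-/-, immediate early and inflammatory genes were lower before stimulation. Basp1, a membrane-associated signalling protein gene, fell from 136 ± 3.54 to 2.21 ± 0.321 CPM (n = 2), a log2 change of -5.94 (SE 0.06, adjusted p = 1.05e-76). NF-kB pathway genes fell in 21 of 21 cases (median -1.21), immediate early genes in 21 of 23 (-1.61) and cytokine genes in 17 of 21 (-1.81), with adjusted p = 0.0118, 0.0118 and 0.0107 with an estimated correlation, among them Ptgs2 (-4.07), Egr1 (-3.92) and Cxcl2 (-3.45). Cell cycle genes fell in 23 of 24 (-1.27) and monocyte genes in 11 of 13 (-3.13), with adjusted p = 0.0107 and 0.0124 with an estimated correlation. Specific granule genes rose in 10 of 11 (0.94, adjusted p = 0.0118 with an estimated correlation), with Camp, the cathelicidin gene, up by 1.47. Olfm4, a specific granule protein gene, rose from 174 ± 2.74 to 1150 ± 14.5 CPM (2.73, SE 0.02). At least 2-fold, 759 genes were higher and 1935 lower.

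With zymosan the IRF5-/- line was at least 2-fold higher at 802 genes and lower at 2023. Basp1 stood at 4.95 ± 0.279 against 963 ± 16.6 CPM in wild type (n = 2; log2 change -7.61, SE 0.05, adjusted p = 4.49e-89). Cytokine genes were lower in 15 of 21 cases (median -0.41, adjusted p = 0.0141 with an estimated correlation), cell cycle genes in 24 of 24 (-1.64) and specific granule genes higher in 11 of 11 (0.97), both with adjusted p = 0.00541 with an estimated correlation. For the NF-kB list the median (0.22) and the test were positive and the mean (-0.33) was negative, as for adhesion and migration (median 0.07, mean -0.12, and -0.11 for the median with total-count scaling). These calls were lost with an estimated correlation, at adjusted p = 0.108 and adjusted p = 0.254. Ptgs2 rose by 7.73 on the log2 scale against 4.40 in wild type and Egr1 by 5.27 against 1.05. Their lower levels with DMSO (log2 changes of -4.07 and -3.92) made up all or most of these differences. The response was larger in 18 of 21 NF-kB pathway genes (median difference 1.29), 22 of 23 immediate early genes (1.39) and 14 of 21 cytokine genes (1.49), each with adjusted p = 0.00208 with an estimated correlation. It was smaller for Runx3 (-1.85) and for Tnfsf14 (-1.69), a TNF family ligand gene. The difference was called for 4583 genes, 1065 of them at least 2-fold.

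Cells labelled RELB-/- lost interferon stimulated and eosinophil transcripts and gained specific granule ones. Prg2, the eosinophil major basic protein gene, fell from 2962 ± 51 to 203 ± 0.249 CPM (n = 2), a log2 change of -3.87 (SE 0.02, adjusted p = 1.59e-93), and eosinophil and mast cell genes fell in 8 of 9 cases (median -3.81, adjusted p = 0.0266 with an estimated correlation). Interferon stimulated genes fell in 21 of 22 (-2.24, adjusted p = 0.00591 with an estimated correlation), with Rtp4 at -4.05. NF-kB pathway genes fell in 20 of 21 (-1.19, adjusted p = 0.00802 with an estimated correlation) and immediate early genes in 22 of 23 (-1.27, adjusted p = 0.0063 with an estimated correlation). Azurophil granule genes fell in 6 of 7 (-1.73, adjusted p = 0.03 with an estimated correlation), with Mpo, myeloperoxidase, at -2.54. Specific granule genes rose in 10 of 11 (1.42, adjusted p = 0.00591 with an estimated correlation), with Ltf at 2.33 and Olfm4 at 2.35. At least 2-fold, 557 genes were higher and 1535 lower.

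With zymosan, RELB-/- cells were at least 2-fold higher at 473 genes and lower at 1768. Areg, the amphiregulin gene, stood at 12.8 ± 0.126 against 186 ± 4.50 CPM in wild type (n = 2; log2 change -3.86, SE 0.06, adjusted p = 9.13e-62). Interferon stimulated genes were lower in 22 of 22 cases (median -2.40), and specific granule genes higher in 10 of 11 (1.48), both with adjusted p = 0.00346 with an estimated correlation. Azurophil granule genes were lower in 7 of 7 (-2.18, adjusted p = 0.0176 with an estimated correlation) and NF-kB pathway genes in 16 of 21 (-0.24, adjusted p = 0.0409 with an estimated correlation). Ptgs2 rose by 7.41 on the log2 scale against 4.40 in wild type and Egr1 by 4.44 against 1.05, while Nfil3 fell by 0.42 where wild type rose by 0.94. For Ptgs2 and Egr1 the lower levels with DMSO (log2 changes of -3.07 and -3.05) made up all or most of the difference. The response was larger in 17 of 21 NF-kB pathway genes (median difference 0.99) and 20 of 23 immediate early genes (1.09), both with adjusted p = 0.00547 with an estimated correlation. The difference was called for 4330 genes, 908 of them at least 2-fold.

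**Figure D4:**
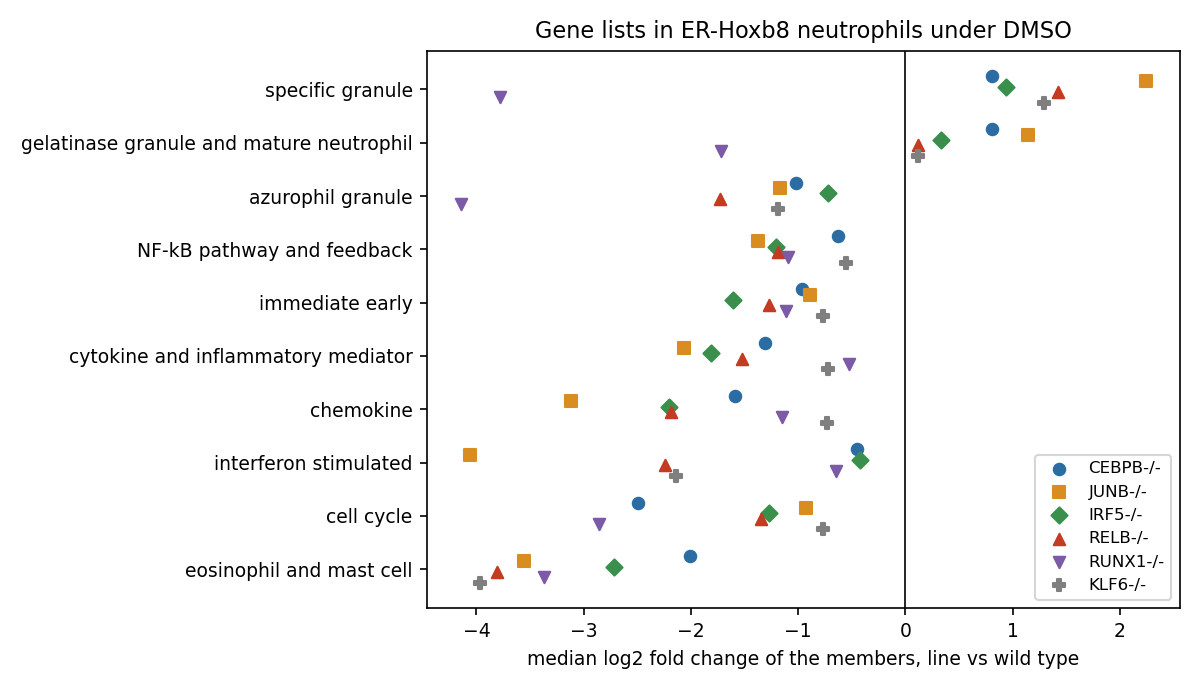
Median log2 fold change (x axis) of 10 gene lists (y axis) in each of 6 lines labelled knockout against wild type under DMSO; each symbol is a line. Specific granule genes were lower in RUNX1-/- cells (-3.78) and higher in the JUNB-/- line (2.24), and eosinophil and mast cell genes were lower in all 6 lines.

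Cells labelled RUNX1-/- lacked much of the neutrophil granule programme. Ngp, a specific granule protein gene, fell from 1795 ± 11 to 33.3 ± 0.969 CPM (n = 2), a log2 change of -5.75 (SE 0.02, adjusted p = 8.52e-77). Specific granule genes fell in 10 of 11 cases (median -3.78, adjusted p = 0.0246 with an estimated correlation), with Cd177 at -4.54, and gelatinase granule genes in 13 of 14 (-1.72, adjusted p = 0.0246 with an estimated correlation), with Retnlg at -4.06 and S100a9 at -2.69. Ly6g, the neutrophil surface marker gene, fell by 5.48 on the log2 scale and Ly6c2 by 7.30. NF-kB pathway genes fell in 18 of 20 cases (-1.09, adjusted p = 0.0192 with an estimated correlation), with Nfkbiz at -3.87, and Il1b fell by 4.16 on the log2 scale. Cell cycle genes fell in 23 of 24 cases (-2.86, adjusted p = 0.0246 with an estimated correlation). Matk, a kinase gene of haematopoietic cells, rose by 5.49 and Serpinb2, a plasminogen activator inhibitor gene, by 4.17. The median of the azurophil granule list was -4.14 and it was not called (adjusted p = 0.055). The eosinophil and mast cell list fell as well, with a median of -3.37. At least 2-fold, 1668 genes were higher and 2109 lower.

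Cells labelled KLF6-/- had fewer interferon stimulated, monocyte and glycolysis transcripts. Olfm4 rose from 251 ± 3.43 to 2586 ± 42.7 CPM (n = 2), a log2 change of 3.36 (SE 0.02, adjusted p = 9.47e-69), and specific granule genes rose in 10 of 11 cases (median 1.29, adjusted p = 0.0131 with an estimated correlation), with Ltf at 2.09. Interferon stimulated genes fell in 22 of 22 (-2.14) and NF-kB pathway genes in 19 of 20 (-0.55), both with adjusted p = 0.0111 with an estimated correlation. Monocyte genes fell in 12 of 13 (-2.70, adjusted p = 0.0177 with an estimated correlation). Glycolysis genes fell in 14 of 17 (-0.60, adjusted p = 0.0346 with an estimated correlation), with the enzyme genes Tpi1 at -1.68 and Ldha at -1.54. Hypoxia response genes fell in 12 cases (-0.83, adjusted p = 0.027 with an estimated correlation). Basp1 (-5.19), Epx (-4.62), the acute phase gene Saa3 (-3.88), Ly6g (-2.69) and Icam1 (-2.41) fell as well. At least 2-fold, 663 genes were higher and 2161 lower.

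Taking genes that zymosan raised in the wild type of the other set, the response to zymosan was larger in all 4 lines tested. The median difference in response was 0.71 in CEBPB-/- (2017 genes; 1146 called larger and 91 called smaller), 0.44 in JUNB-/- (905 larger, 247 smaller), 0.28 in IRF5-/- (2274 genes; 858 larger, 235 smaller) and 0.27 in RELB-/- (874 larger, 149 smaller). For genes raised by a log2 change of 2 or more these were 1.14, 0.71, 0.65 and 0.52, and without the first DMSO library of its wild type the JUNB-/- value was 0.29. By camera with an estimated correlation the lists had p = 5.36e-06, 9.89e-04, 1.55e-05 and 4.76e-06. Before zymosan the same genes had a median of -0.51, -0.56, -0.47 and -0.35 against wild type, and after zymosan 0.28, -0.05, -0.09 and -0.10. Total-count scaling moved the median of all genes in knockout against wild type by -0.35 and -0.58 in CEBPB-/- cells (DMSO and zymosan), -0.55 and -0.52 in JUNB-/-, -0.12 and -0.18 in IRF5-/-, -0.14 in KLF6-/- and 0.36 in RUNX1-/-. With 2 libraries per group, a difference between lines includes any difference between their cultures.

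**Figure D5:**
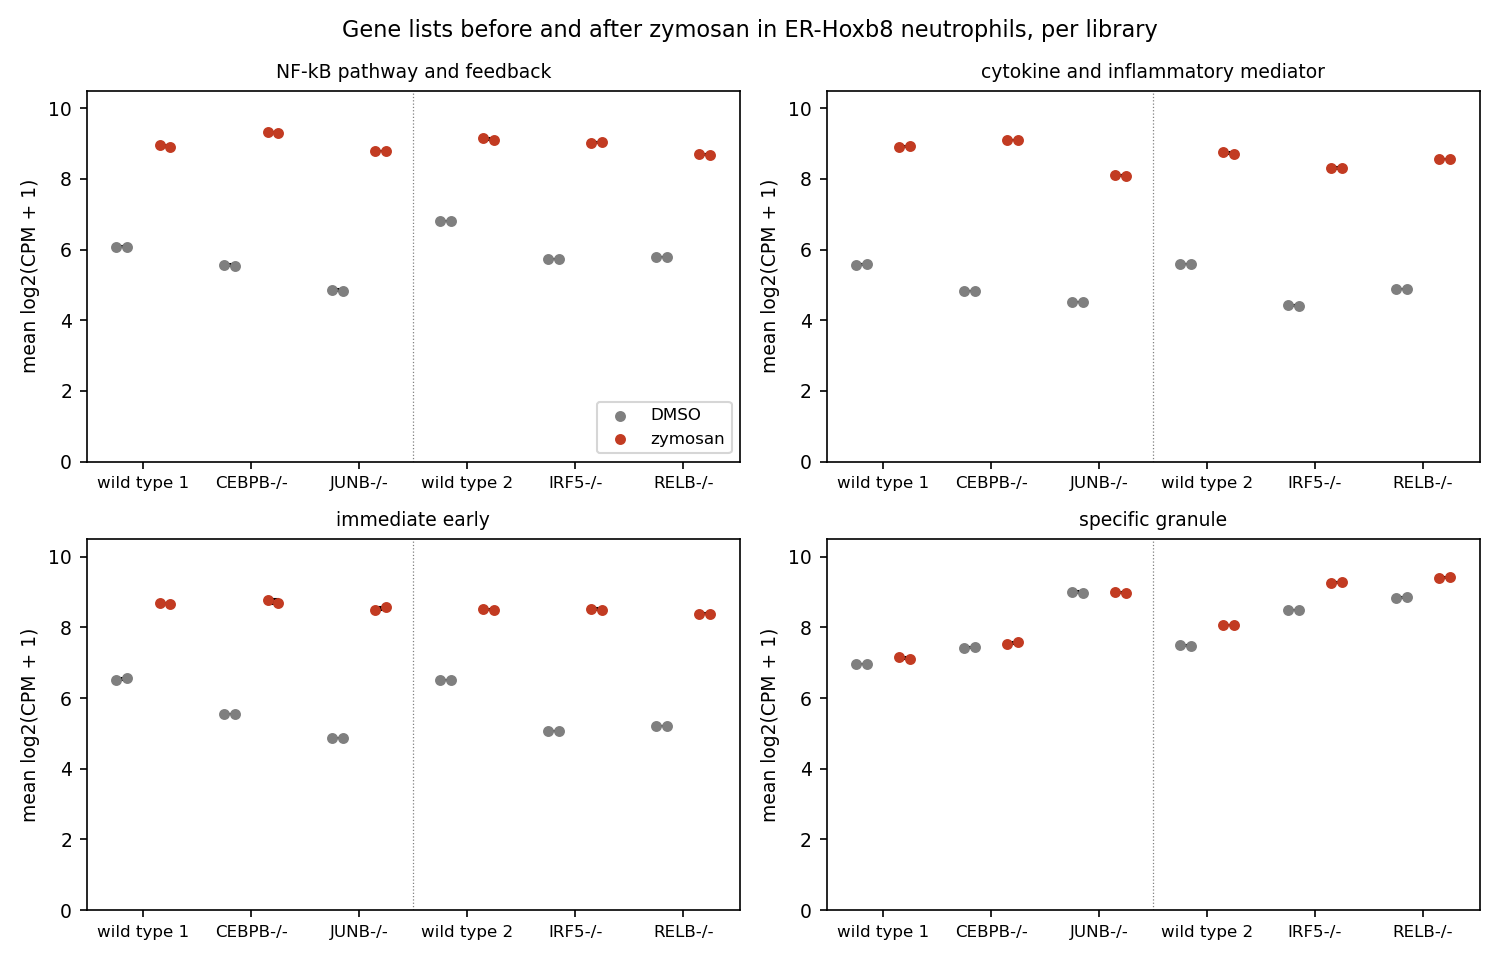
Mean log2(CPM + 1) of 4 gene lists (y axis) in 6 ER-Hoxb8 lines (x axis) under DMSO and zymosan; points are libraries, the bar is the mean and the whiskers are the SD (n = 2). In RELB-/- cells the NF-kB pathway list had a median log2 change against wild type of -1.19 under DMSO and -0.24 under zymosan.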

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

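Tests of a mislabelled sample and of low depth for exudate library 5, of the wild-type reference, total-count scaling and a lower starting level for the zymosan response, and of other splits of the samples were chosen only after the result was seen; that of a lower starting level was recast more than once after its results were seen, and an earlier form that took genes as independent had excluded it in CEBPB-/- and RELB-/- cells. Of 70 groups of 5 libraries that were checked for a library far from the others, 11 had one, where chance gives about 1 in 20, or 3.5.

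Exudate library 5 lay far below the other exudate libraries in its scores for cytokine (2.27), chemokine (2.38), NF-kB pathway (2.53), immediate early (4.45), interferon stimulated (2.21) and pattern recognition genes (6.04). It held 0.0765 CPM of Ccl3 where the others held 7095 ± 1848 (n = 4), and 12210 CPM of the granule gene Ngp against 1368 ± 960, genes chosen after their values were seen. Low depth was excluded, since at 19.1 M read pairs it was the deepest tissue library. A wrong label cannot be told apart from a true difference: its mean rho was 0.397 with the other exudate libraries and 0.460 with blood (difference -0.063), but exudate libraries 1 to 4 also had a higher rho with another tissue, membrane (0.496 to 0.543), than with exudate (0.459 to 0.498), as all blood libraries had with membrane or bone marrow. A library batch given by the tag could not be decided (difference in rho 0.027), and cells of the exudate that had not responded stay open as an untested biological explanation.

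In exudate the Relb level of a library (241.7 CPM) and the scores for ribosomal protein (3.30), T and NK cell (1.73) and platelet genes (3.62) were also far from the others. In blood a library had a dendritic cell and MHC class II score of 2.25, far from the rest. Blood libraries 1 and 2 were closer in rho to membrane (0.534 and 0.56) than to blood (0.531 and 0.54), and whether their labels are wrong was not tested.

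The response to zymosan differed from that of wild type in all 4 lines tested, at 5294 genes in CEBPB-/-, 5619 in JUNB-/-, 4583 in IRF5-/- and 4330 in RELB-/- cells. For genes that zymosan raised, the response was on balance larger in all 4. A weak response in one of the wild types was excluded as the whole cause: over the 1577 genes raised in both wild types, 4 of 4 lines had a median difference above 0 against the wild type of the other set (1.12, 0.83, 0.25 and 0.16), where their own wild type differed from it by 0.30 in set 1 and -0.30 in set 2. The choice of TMM was not the whole cause either, since the lowest median with total-count scaling was 0.22. Scaling is not excluded as part of the cause. Total-count scaling took the medians from 0.71 to 0.48 in CEBPB-/-, 0.44 to 0.46 in JUNB-/-, 0.28 to 0.22 in IRF5-/- and 0.27 to 0.25 in RELB-/- cells. A lower level before zymosan cannot be told apart from other causes in any of the 4 lines: genes within a log2 change of 0.25 of wild type before zymosan had a median difference of 0.51 in CEBPB-/-, 0.21 in JUNB-/-, 0.09 in IRF5-/- and 0.10 in RELB-/- cells, or 0.14, 0.05, -0.04 and 0.09 with total-count scaling, and the lowest 95% limit with and without any one library, widened for correlation between genes and less their shortfall before zymosan, was -0.02, -0.15, -0.2 and -0.01; whether loss of the factors causes the larger response was not tested.

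The zymosan response also differed between the wild types of both sets at 5337 genes in a joint fit, 1273 of them at least 2-fold, and their levels differed at least 2-fold at 3448 genes with DMSO and 3603 with zymosan.

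In all 6 lines, 291 genes were at least 2-fold lower than in wild type, and 1 gene, Plxnb3, was higher. In simulated unchanged lines set against shared wild-type libraries 0 of 11788 genes were lower. The simulated libraries held the spread of replicates but no difference between cultures, and at most 1 gene was called in any line. This 0 therefore says nothing on differences between cultures. With the wild type of the other set, 80.4% of the genes (234) were also lower in all 4 lines. This cannot exclude a peculiarity shared by the wild types, since the genes were chosen as lower than both of them. With total-count scaling 90.03% (262) stayed lower in all 6 lines, so the choice of TMM alone did not make most of them lower. Total-count scaling moved the median of all genes down in CEBPB-/-, JUNB-/-, IRF5-/- and KLF6-/- cells, and up in RUNX1-/- cells. Genes chosen as lower were thus likely to stay lower in most lines, and scaling as such cannot be excluded. A smaller share of eosinophil-like cells in the lines cannot be told apart from other causes, because over the 6 lines the median of the eosinophil and mast cell list and that of the other genes gave rho 0.314 (exact p = 0.564). How the lines were made and grown, against wild type, is untested.

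The 22 genes between exudate and bone marrow exceeded every one of the other 55 splits, with 1 of 56 giving as many, the real one. The highest of the others called 2 genes. This is the smallest share that 56 splits can give, in a test chosen after the result was seen. The count also fell to 0 without any one of the bone marrow libraries, so chance is less likely but not excluded. For exudate against blood the real count is 0, so all 100 of the 100 drawn splits gave as many by construction, and the count says nothing on chance. The highest of the others was 13, the cause of which was not tested. For the 2 genes between blood and bone marrow chance is not excluded either, with 4 of 56 splits giving as many. The highest of the other splits called 23 genes, and why was not tested.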

How the results depend on the processing

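The alternatives with total-count scaling, voom, library weights, the column tags and only blood libraries 3 to 5 were chosen only after the data were seen. All 6 named genes of the tissues, those between exudate and bone marrow, kept direction and call in DESeq2, without a filter, with the tag as a term and in libraries of tag 100; all 6 lost the call with only the compared groups, 3 in voom, 2 with weights, 3 with RLE and 2 with total-count scaling. Without 1 library their results were weaker in 42 cases and the same in 6. All 154 named gene results of ER-Hoxb8 cells were kept in DESeq2, without a filter, in voom, with weights, with only the compared groups and with RLE. Fits without 1 library leave 1 library in a group of these cells. The spread then comes from the other groups, so calls in such fits are not counted as a check. With total-count scaling 153 were kept, and Cebpb in CEBPB-/- cells with DMSO reversed from 0.05 to -0.31, the cause of which was not tested.

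Residuals gave little sign that replicate numbers pair the libraries, but pairing is not excluded. Residual correlations of same-numbered ER-Hoxb8 libraries exceeded 0.1 in 1 of 15 cases in set 1, 1 of 15 in set 2 and 3 of 10 for the later table; with a block all 154 named gene results were kept, and 218 lists were called against 217. Tissue columns carry a tag and a number from m1 to m4, which match no number in the sample titles. Residuals of libraries with the same tag and number correlated over 0.1 in 2 of 11 pairs (median -0.015), and 3 of 13 libraries correlated best with such a partner; for the number alone it was 4 of 23 pairs and 4 of 14 libraries. A block by tag and number raised the counts of genes below to 88, 93, 9, 71, 290 and 273, in the order of the comparisons, and one by number gave 2, 0, 0, 5, 117 and 154; tissue lists called were 73 with the block by tag and number against 63, with 4 lost. These added fits kept the 6 named genes, gave correlations with culture of 0.225 and 0.242 (tag and number) and 0.215 and 0.232 (number), and did not call expression near sites less accessible in exudate than in blood (0.21 and 0.1). Why the counts rose was not tested, and the exact permutation tests treat libraries as unpaired as well.

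Calls in the tissues depended on the tool, and the cause was not tested except where fewer libraries were used. Blood against bone marrow (2 genes) gave 1 with RLE, 1 with total-count scaling, 237 in DESeq2, 62 without a filter, 0 with only the compared groups, 43 in voom, 90 with weights, 0 with only blood libraries 3 to 5, and 0 to 2 without 1 library. Membrane against blood (0) gave 1087 in DESeq2, 13 without a filter, 172 in voom, 235 with weights, 1 in libraries of tag 300 and 7 with only blood libraries 3 to 5. Exudate against membrane (0) gave 792, 16, 52 and 52 in DESeq2, without a filter, in voom and with weights. Exudate against blood (0) gave 1003, 80, 174 and 166 in the same order, 15 in libraries of tag 100, 31 with only blood libraries 3 to 5, 264 when exudate library 5 was left out as well, and 0 to 14 without 1 library (14 without exudate library 5). Exudate against bone marrow (22) gave 1414, 266, 968 and 1421 in the same order, 0 with only the compared groups, 188 with the tag as a term, 237 in libraries of tag 100, and 0 to 197 without 1 library (0 without bone marrow library 1, 2 or 3, 197 without exudate library 5). Membrane against bone marrow (2) gave 1421, 140, 772 and 1175 in the same order, 128 with only the compared groups, 31 with the tag as a term, and 0 without bone marrow library 1, 2 or 3.

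A 2-fold threshold lowered counts by construction, to 4720 and 4010 for zymosan in the wild types of sets 1 and 2. With DMSO it gave 3208 for CEBPB-/-, 4563 for JUNB-/-, 2694 for IRF5-/-, 2092 for RELB-/-, 3777 for RUNX1-/- and 2824 for KLF6-/-. With zymosan it gave 3576, 5020, 2825 and 2241 for the first 4 of these, and for their interactions 1444, 1622, 1065 and 908. An estimated correlation lowered list calls from 63 to 2 in the tissues and from 217 to 103 in ER-Hoxb8 cells.

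The correlation of exudate against blood with zymosan in culture (0.189 and 0.210) was 0.131 and 0.145 in DESeq2, 0.14 and 0.161 without a filter, 0.239 and 0.268 with only the compared groups, 0.267 and 0.285 in voom, 0.292 and 0.314 with weights, 0.252 and 0.276 with the tag as a term, 0.259 and 0.276 in libraries of tag 300, 0.269 and 0.291 with only blood libraries 3 to 5, and 0.312 and 0.335 when exudate library 5 was left out as well. Without 1 library it was 0.168 to 0.242 and 0.179 to 0.264. Expression near sites less accessible in exudate than in blood reversed from 0.57 to -0.07 in libraries of tag 300, and lost its call in DESeq2 (0.27), with only the compared groups (0.15), in voom (0.03), with weights (0.05), without exudate library 5 (0.28), with only blood libraries 3 to 5 (0.32) and without exudate library 5 as well (0.2). Near sites less accessible in exudate than in bone marrow the difference of -0.27 was called within 10000 bp (-0.63), with RLE (-0.29), with total-count scaling (-0.31) and without exudate library 5 (-0.52) or bone marrow library 2 (-0.28), and not within 100000 bp (-0.09). Near sites less accessible in blood than in bone marrow (-0.33) it was called in DESeq2 (-0.5), without a filter (-0.72), with weights (-0.47) and without blood library 5 (-0.61) or bone marrow library 2 (-0.58). Other calls lost were those for more accessible sites in blood (0.21) and in membrane (0) against bone marrow in DESeq2, and that for less accessible sites in membrane against bone marrow without a filter (0). Shares of sites near gene starts kept their side of the threshold at 500 and 5000 bp, and shared sites stayed within 1.5 times with a reciprocal overlap of 50%. The larger response to zymosan in the lines (0.71, 0.44, 0.28 and 0.27) was 1.14, 0.71, 0.65 and 0.52 for genes raised by a log2 change of 2 or more, and 0.59 to 0.70, 0.29 to 0.44, 0.27 to 0.40 and 0.26 to 0.40 without 1 library.

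The share of called genes that rose depended on scaling. Total-count scaling took it from 47.7% to 23.3% in CEBPB-/- cells with DMSO and from 51.5% to 18.7% with zymosan, from 46.3% to 20.4% and 51.1% to 27.9% in JUNB-/-, from 54.2% to 42.9% and 49.0% to 32.6% in IRF5-/-, from 50.6% to 71.3% in RUNX1-/- and from 46.4% to 33.7% in KLF6-/- cells. What greater depth would change was not tested. Motifs in sites, with the alternatives of no stratification and of the central part of each site, were not run for lack of a genome sequence. Genes called both in exudate against blood and in culture numbered 0 and gave no value; against bone marrow 20 were called with set 1 (70% with the same sign, r 0.504) and 16 with set 2 (75%, r 0.892). No other deposited table holds the zymosan, RUNX1-/- or KLF6-/- comparisons.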

Other observations

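The comparisons of energy, ribosomal and azurophil granule genes below were singled out only after their values were seen; the test of genes near opened sites was set before its result was seen. Oxidative phosphorylation genes scored 4.90 ± 0.07 log2 CPM in bone marrow (n = 3), 3.68 ± 0.64 in blood (n = 5), 2.93 ± 0.64 in exudate (n = 5) and 2.63 ± 0.42 in membrane (n = 2). All exudate libraries lay below all bone marrow libraries (exact permutation p = 0.0179, the smallest that 56 splits can give; 0.0716 after adjustment over the lists). Ribosomal protein genes scored 3.37 ± 0.10 in bone marrow and 2.10 ± 0.67 in exudate (exact permutation p = 0.0357, adjusted 0.125). Some lists of other cell types moved with them: erythroid (difference -3.23), B cell (-2.1) and T and NK cell genes (-2.15) were also lower in all exudate than in all bone marrow libraries, each with exact permutation p = 0.0179 (adjusted 0.0716). Others rose: monocyte (1.25) and eosinophil and mast cell genes (1.4) in all exudate libraries, and dendritic cell (0.99) and platelet genes (0.85) on average. Their exact permutation p lay between 0.0893 and 0.446. The azurophil granule list, with 2 measured genes, scored 3.03 ± 0.48 in blood and 0.93 in exudate, with libraries between 0.11 and 2.12 (exact permutation p = 0.00794, adjusted 0.222).

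In all 6 zymosan-treated ER-Hoxb8 lines, wild types included, 1244 genes rose and 824 fell at least 2-fold. Lines labelled as knockouts of different factors resembled each other across sets under DMSO, with r = 0.695 across genes for CEBPB-/- and IRF5-/- and 0.599 for CEBPB-/- and RELB-/-. RUNX1-/- cells did not resemble them to this degree, with r = 0.162 to CEBPB-/- and -0.029 to JUNB-/-. Among the genes lower in all 6 lines were 6 of 8 eosinophil and mast cell genes (adjusted exact p = 1.23e-07), 7 of 24 cell cycle genes (1.31e-05) and 5 of 13 monocyte genes (7.15e-05).

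One hypothesis was that genes near sites opened in exudate would be lower after zymosan, more often than other genes, in all 4 lines labelled knockout. The data did not bear this out: the odds ratio of being at least 2-fold lower in zymosan was 0.964 in JUNB-/-, 0.932 in RELB-/-, 0.543 in CEBPB-/- and 0.397 in IRF5-/- cells. Such genes were more often at least 2-fold higher in CEBPB-/- cells with zymosan (199 of 1079, 18.4%, against 7.4%; odds ratio 2.83, exact p = 2.6e-27), with odds ratios of 1.17, 1.21 and 1.07 in the JUNB-/-, IRF5-/- and RELB-/- lines. Whether these genes need the factors was not tested, since transcripts of the targeted genes remained and protein was not measured. Before zymosan the odds ratio was 2.54 in RUNX1-/- cells (283 of 1071 genes, 26.4%, against 12.4%; exact p = 1.95e-30), 2.36 in RELB-/-, 1.64 in IRF5-/-, 1.44 in JUNB-/- and 1.24 in KLF6-/- cells (adjusted exact p = 0.034), and 1.1 in CEBPB-/- cells (adjusted exact p = 0.309); for higher genes it was 0.549 in RUNX1-/- cells (exact p = 1.95e-07).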
